A study of Mus musculus with 8 samples.

How the data were processed

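Total RNA was sequenced from tissue of adult male C57Bl6J mice, in 8 libraries that form 4 groups of 2. The nucleus accumbens (NAc) was sampled after place-preference conditioning with cocaine and from mice kept in the home cage, and the medial prefrontal cortex (mPFC) was sampled after social defeat and from home-cage mice. Groups were taken from the sample titles and treatment labels. In this text the mPFC home-cage libraries are replicates 1 and 2 and the social defeat libraries are replicates 1 and 2, in the order of the deposited samples. The labels do not say whether the replicates of a group are separate animals, so p-values measure only the spread between these samples.

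The authors aligned reads to the mm10 build with STAR 2.7.1a and counted them with featureCounts. The deposited tables hold raw counts per gene symbol, 1 table per region, each with 33885 symbols in the same order. The featureCounts version, the annotation release and the options for strand, introns and reads with several alignments are not given in the sources used here. All values in both tables were whole numbers, and no normalization had been applied. Gene coordinates, on GRCm38 (mm10), and gene types were taken from GENCODE release M21 by symbol, which matched 32962 symbols. A total of 9185 symbols had 0 counts in all 8 libraries, among them the 15 mitochondrially encoded genes of the list below, for which no value can be given.

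Library totals ranged from 111901829 to 179479978 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The floor for a group with 0 counts was 3 counts over the group.

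Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For each comparison the low-count filter filterByExpr, TMM factors, estimateDisp, glmQLFit and glmQLFTest of edgeR were used with default settings, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. The 4 comparisons were cocaine against home cage in NAc, social defeat against home cage in mPFC, NAc against mPFC in home-cage mice, and the difference between the 2 responses, as a contrast of all 8 libraries. Standard errors (SE) of log2 fold changes were the absolute log2 fold change divided by the square root of the quasi-likelihood F. An exact permutation test of 2 against 2 values cannot give a two-sided p below 0.33, so single genes were tested only in models fitted across all genes. Levels are in CPM, edgeR's counts scaled to a common library size, with TMM factors over the 8 libraries, given as mean and standard deviation (SD).

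The comparisons, their tests, the alternatives and 23 gene lists were chosen before the data were examined, except where another choice is named as made after seeing the data. The lists held rapid immediate early genes, delayed activity-regulated genes, glucocorticoid-responsive genes, ERK pathway feedback regulators, heat shock and chaperone genes, circadian clock genes, glutamate and GABA-A receptor subunits, interferon-stimulated genes, mitochondrially encoded genes, cytosolic ribosomal protein genes, replication-dependent histone genes, and markers of striatal projection neurons, cortical glutamatergic neurons, interneurons, basal forebrain, septum and thalamus, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus and ependyma, meningeal fibroblasts, and blood cells. Each list with at least 3 tested members (22 lists) was tested with camera of limma on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The fry test of limma was run as a description. Counts of list members that passed were also taken with p-values adjusted over the list alone.

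Genes are named by a rule fixed with the comparisons. Among genes that passed, that had both libraries of one group above both of the other and a mean CPM of at least 1 in a group, the 8 with the largest positive and the 8 with the largest negative log2 fold change are named, with provisional gene models skipped. Fos, Fosb, Egr1, Arc, Npas4, Junb, Nr4a1 and Dusp1 are named in both treatment comparisons whether or not they passed. From each other list, up to 2 tested members with the smallest p are named, and 4 members of the striatal and cortical lists with the largest absolute fold change in the regional comparison. Where fewer than 5 genes passed, the 5 with the smallest p in each direction are named. Other genes were chosen after their values were seen, and this is said where they appear.

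A striatal minus cortical score was computed for each library as the mean log2 CPM of the striatal list minus that of the cortical list. The overlap of the treatment responses was tested with Fisher's exact test over genes tested in both comparisons, in which genes are not independent replicates. Recovery was tested on simulated data with the dispersions and depths of each comparison and 200 genes changed 1.5-fold, 2-fold or 4-fold. Libraries were drawn independently. For fits with the score as a covariate, the fitted effect of the score was built into the simulated means.

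Alternatives were DESeq2 size factors in edgeR, upper-quartile factors, no low-count filter, a mean count of at least 50, the DESeq2 Wald test, robust and legacy quasi-likelihood fits, factors without ribosomal RNA and mitochondrial genes, an adjusted p under 0.10, a single fit of all 8 libraries, the replicate number as a block, camera with a prior count of 0.5, and leaving out each library in turn. In edgeR 4.0.16 the default fit is the legacy fit, so that alternative is identical to the reported one. A newer quasi-likelihood fit (legacy=FALSE) and the striatal minus cortical score as a covariate were added after seeing the data. Where leaving out a library left 1 in its group, the lone library was assumed to vary like the other group. No library and no column of counts was left out of the reported fits.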

Results

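Total RNA was measured in 2 brain regions of adult male C57Bl6J mice, an inbred strain. The NAc, a ventral striatal region that takes part in reward, came from tissue dissected 15 minutes after conditioning in a place-preference apparatus with cocaine at 7.5 mg/kg (n = 2) and from home-cage mice (n = 2). The mPFC came from tissue dissected 15 minutes after social defeat, in which an aggressive CD1 male attacks the mouse (n = 2), and from home-cage mice (n = 2). Total counts were 139116911 and 141245049 in the cocaine libraries and 179479978 and 136524731 in the NAc home-cage libraries. They were 131159838 and 140624648 in the social defeat libraries and 135242756 and 111901829 in the mPFC home-cage libraries. The 10 most abundant genes held between 3.36% and 4.12% of the counts of a library. Malat1, a nuclear noncoding RNA, held 0.615% of all counts, and the neuronal genes Dpp10, Rbfox1, Csmd1 and Dlg2 were also among the 10, named here after their values were seen.

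The first comparison asked which RNAs differed in NAc shortly after cocaine conditioning. None of the rapid immediate early genes, which neurons transcribe within minutes of activity, passed over all genes in the reported edgeR fit. Fos, a subunit of the AP-1 transcription factor, averaged 16.1 ± 2.34 CPM (SD, n = 2) after cocaine and 4.87 ± 4.05 CPM (SD, n = 2) in home-cage mice. Npas4, a neuronal activity-dependent transcription factor, averaged 47.2 ± 3.57 CPM (SD, n = 2) after cocaine and 14.7 ± 2.93 CPM (SD, n = 2) in home-cage mice. Egr2, a zinc finger transcription factor, averaged 4.72 ± 0.0381 CPM (SD, n = 2) against 1.99 ± 0.126 CPM (SD, n = 2). Arc, which encodes a synaptic protein, averaged 97.8 ± 0.31 CPM (SD, n = 2) against 50.6 ± 17.2 CPM (SD, n = 2).

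Of the 34 tested rapid immediate early genes, 30 had a positive log2 fold change, with a median of 0.34, and 0 passed over all genes. Adjusted over the list alone, 4 were higher: Dusp1, Egr2, Fosb and Npas4. Their log2 fold changes were 1.69 (SE 0.169) for Npas4, 1.25 (SE 0.132) for Egr2, 0.75 (SE 0.0977) for Fosb and 0.67 (SE 0.119) for Dusp1, a phosphatase of MAP kinases. Among the other members fixed for naming, Fos had 1.73 (SE 0.656), Arc 0.95 (SE 0.25), Junb 0.70 (SE 0.167), Nr4a1 0.49 (SE 0.210) and Egr1 0.20 (SE 0.133). Without NAc home-cage replicate 1 or 2 in turn, Fos had 1.06 and 3.0, Nr4a1 0.23 and 0.80, and Egr1 0.06 and 0.35. In 21 of the 34 genes, and in 8 of the 8 genes fixed for naming, both cocaine libraries lay above both home-cage libraries, where chance gives 16.7% of genes and 11.8% of all tested genes did so. Camera called the list higher (adjusted p = 7.87e-14), the estimated correlation did not (adjusted p = 0.962), and the fry p was 0.0915. The list call held without each of the 4 libraries in turn.

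**Figure D1:**
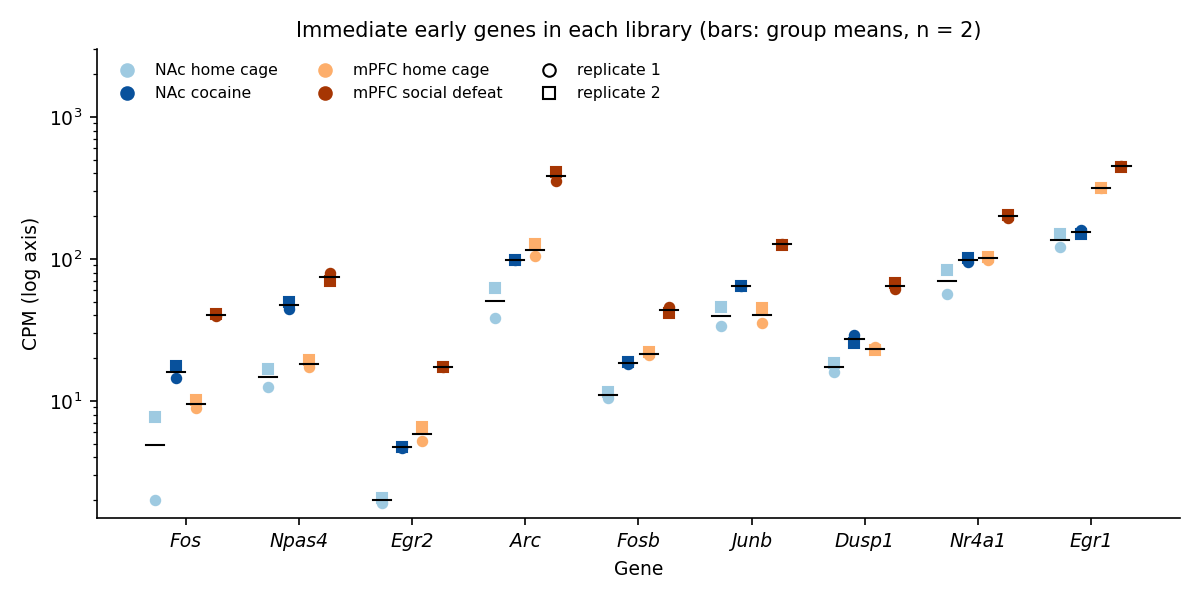
Level in CPM (log axis) of immediate early genes in each of the 8 libraries, with points for single libraries and bars for group means (n = 2). In NAc, Npas4 averaged 47.2 CPM after cocaine and 14.7 CPM in home-cage mice, and in mPFC 74.6 CPM after social defeat and 18.3 CPM in home-cage mice.

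Over all 18418 genes tested in NAc, edgeR passed 0 genes, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 211 genes, 165 higher and 46 lower, where chance gives 921. This fit keeps the difference between replicate numbers, described below, in its spread, so passing 0 genes does not show that none responded. With the replicate number as a block, an alternative chosen before the data were seen, 38 genes passed, 33 higher and 5 lower. In that fit 1307 genes had an unadjusted p under 0.05. The labels do not say that the number marks a batch. The DESeq2 Wald test passed 4 genes, all higher: Npas4 (adjusted p = 6.9e-12), Egr2 (adjusted p = 1.19e-07), Fosb (adjusted p = 0.00114) and Ccn1 (adjusted p = 0.00806), the last named after its value was seen. Besides Npas4, Egr2, Fosb and Dusp1, the gene with the smallest p among those higher was the microRNA gene Mir132, with a log2 fold change of 1.30 (SE 0.206). The 5 with the smallest p among those lower were Cacng6, a calcium channel subunit, at -0.72 (SE 0.191), Mir1247 at -1.91 (SE 0.479), Pdp1, a phosphatase of pyruvate dehydrogenase, at -0.34 (SE 0.0753), Postn, an extracellular matrix protein, at -0.90 (SE 0.190) and Vis1 at -1.94 (SE 0.430). None of these passed in the fit without the block. Mir1247 and Vis1 averaged 0.0283 and 0.0284 CPM after cocaine, so their log2 fold changes rest on few counts.

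Camera called 3 more lists higher after cocaine, and an estimated correlation called none of them. Oligodendrocyte markers, the genes of myelin-forming cells, had positive log2 fold changes in 15 of 15 tested members with a median of 0.37 (camera adjusted p = 2.26e-05), and adjusted p = 0.971 with an estimated correlation. Their mean log2 CPM was 6.27 and 6.11 in the cocaine libraries and 6.18 and 5.38 in home-cage replicates 1 and 2, and without NAc home-cage replicate 2 the direction was down (adjusted p = 0.996). Mag, a myelin glycoprotein, had a log2 fold change of 0.41 (SE 0.248) and Sox10, a transcription factor of the lineage, 0.31 (SE 0.141); without NAc home-cage replicate 1 or 2 in turn, Mag had 0.79 and 0.10 and Sox10 0.49 and 0.16. Glucocorticoid-responsive genes were positive in 17 of 20 members (camera adjusted p = 4e-04), with adjusted p = 0.962 with an estimated correlation, adjusted p = 0.171 without cocaine replicate 1 and adjusted p = 0.115 without NAc home-cage replicate 1. Plekhf1 had 0.45 (SE 0.144) and Tsc22d3, a steroid-induced leucine zipper gene, 0.25 (SE 0.0927). Delayed activity-regulated genes were positive in 18 of 26 members (camera adjusted p = 0.0369), with adjusted p = 0.962 with an estimated correlation. Their call was lost without cocaine replicate 1 (adjusted p = 0.109), cocaine replicate 2 (adjusted p = 0.256) or NAc home-cage replicate 1 (adjusted p = 0.767). Nr4a3, an orphan nuclear receptor, had 1.04 (SE 0.35) and Fosl2, an AP-1 subunit, 0.40 (SE 0.141). Without NAc home-cage replicate 1 these were 0.63 and 0.24, and without replicate 2 Nr4a3 had 1.60. In the fit without the block, 0 members of these 3 lists passed, over all genes and adjusted over the list alone.

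The NAc libraries differed more by replicate number than by treatment, and markers of striatal and cortical neurons followed that difference. Drd2, the dopamine D2 receptor of striatal projection neurons, was 3.33-fold higher in replicate 1 than in replicate 2 after cocaine and 4.77-fold higher in home-cage mice. Fezf2, a transcription factor of deep-layer cortical neurons, had ratios of 0.446 and 0.326, and was chosen after its values were seen. The striatal minus cortical score was 1.5 and -0.43 in cocaine replicates 1 and 2, 1.98 and -0.64 in home-cage replicates 1 and 2, and between -4.52 and -4.41 in the mPFC libraries. The first principal component of the 4 NAc libraries held 79.4% of the variance and separated the numbers. Between the treatments, striatal markers had a median log2 fold change of -0.18 (camera adjusted p = 0.694) and cortical markers -0.02 (camera adjusted p = 0.932). Both lists moved with single libraries: without any 1 NAc library the striatal list passed, up without cocaine replicate 2 or home-cage replicate 1, and down without cocaine replicate 1 or home-cage replicate 2, with camera adjusted p between 3.93e-05 and 0.00996. After cocaine, the median, the mean and the camera direction differed in sign for ERK feedback regulators, receptor subunits, cortical, interneuron and basal forebrain markers, none of them called.

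**Figure D2:**
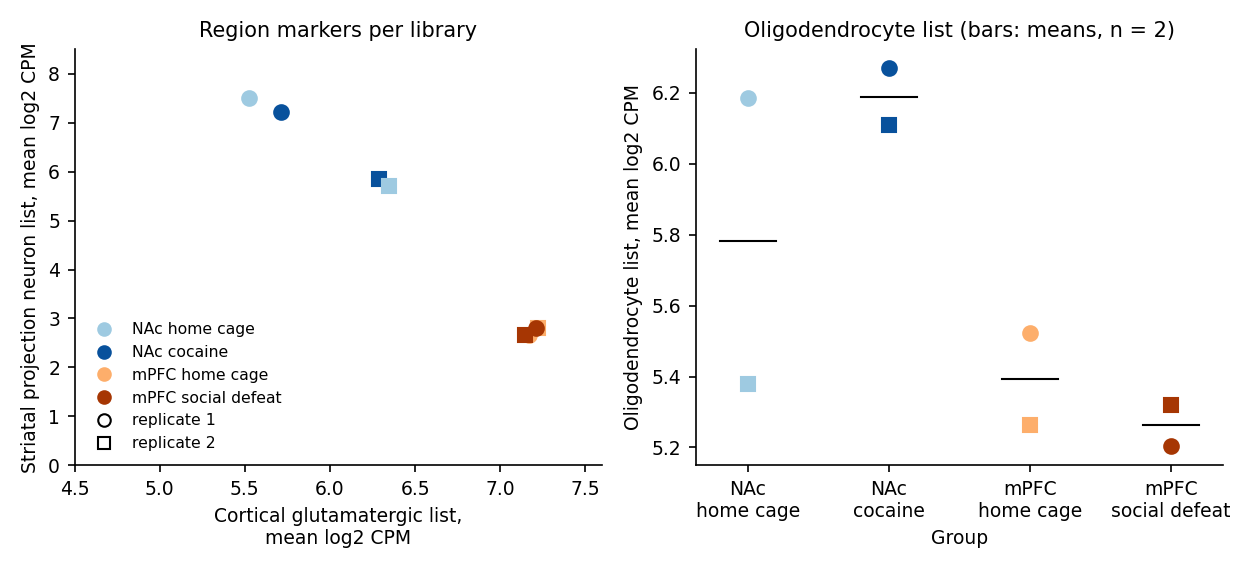
Mean log2 CPM of marker lists, with 1 point per library: on the left the cortical list (horizontal axis) against the striatal list (vertical axis), on the right the oligodendrocyte list by group with bars for group means (n = 2). In NAc the striatal list averaged 7.21 and 5.85 in the cocaine libraries and 7.51 and 5.70 in the home-cage libraries, and the oligodendrocyte list was lowest in home-cage replicate 2, at 5.38.

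With the score as a covariate, a fit chosen after seeing the data that leaves 1 residual degree of freedom, 373 genes were higher and 88 lower after cocaine. They included 17 of the 34 rapid immediate early genes, 14 of the 15 oligodendrocyte markers, and genes high in a single home-cage library, such as Scgn with 397 counts in replicate 2 and 41 in replicate 1, and Calcr with 205 in replicate 1 and 11 in replicate 2. The home-cage mice received no stimulation, so cocaine was not separated from injection, handling and the apparatus. In simulated data, edgeR without the covariate recovered 83.3% of 4-fold, 35.8% of 2-fold and 4.5% of 1.5-fold changes, with 20 false calls among 102. With the covariate it recovered 93.9%, 85.1% and 70.1%, with 9 false calls among 175. Both simulations drew libraries independently, unlike the NAc libraries, which deviated together by number. The simulation with the covariate built the same score into its means. It therefore cannot show false calls that come from a covariate chosen after seeing the data.

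The second comparison asked which RNAs differed in mPFC shortly after social defeat. The only mPFC control was the home cage, so the attack was not separated from handling and the change of surroundings. Several immediate early genes rose. Ccn1, a secreted matrix-associated protein, rose from 2.16 ± 0.267 CPM (SD, n = 2) to 13.9 ± 0.494 CPM (SD, n = 2), and Btg2, an antiproliferative factor, from 5.67 ± 0.293 CPM (SD, n = 2) to 27.0 ± 0.59 CPM (SD, n = 2). Fos rose from 9.50 ± 0.865 CPM (SD, n = 2) to 40.4 ± 0.94 CPM (SD, n = 2), Npas4 from 18.3 ± 1.33 CPM (SD, n = 2) to 74.6 ± 6.89 CPM (SD, n = 2) and Arc from 116 ± 16.9 CPM (SD, n = 2) to 381 ± 37.2 CPM (SD, n = 2). Transcripts of alpha and beta globin, growth hormone and a microRNA locus also rose, and a smaller set of genes fell.

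Of 18027 genes tested, 99 were higher and 28 lower after social defeat in edgeR, and 106 of the 127 were protein coding. A total of 29 rose and 10 fell by more than 2-fold. The genes with the largest increases that met the naming rule were Ccn1 at 6.39-fold (log2 SE 0.112), Btg2 at 4.76-fold (log2 SE 0.0927), Fos at 4.26-fold (log2 SE 0.0874) and Npas4 at 4.08-fold (log2 SE 0.0839), each with adjusted p = 2.43e-28. Gh, which encodes growth hormone, was 4.06-fold higher (log2 SE 0.211, adjusted p = 1.05e-10), with 228 and 229 counts after defeat and 72 and 31 in home-cage mice. Ier2, an immediate early gene, was 3.39-fold higher (log2 SE 0.0992, adjusted p = 4.89e-22). The microRNA genes Mir212 and Mir132 were 3.85-fold (log2 SE 0.117, adjusted p = 1.13e-20) and 3.52-fold higher (log2 SE 0.208, adjusted p = 1.78e-09). Per GENCODE M21, Fos lies on chromosome 12 at 85473890 to 85477273, Npas4 on chromosome 19 at 4984355 to 4990316, Ccn1 on chromosome 3 at 145646976 to 145649981, Btg2 on chromosome 1 at 134075170 to 134079120 and Gh on chromosome 11 at 106300271 to 106301865. Mir212 (75173388 to 75173478) and Mir132 (75173682 to 75173747) lie side by side on the forward strand of chromosome 11. Their reads come from a total RNA library and were not resolved into precursor and mature microRNA. Ovca2, on the reverse strand of the same chromosome at 75175942 to 75178835, had a log2 fold change of 1.40 (SE 0.101, adjusted p = 6.43e-17) and was named after its value was seen; whether the counting kept the strands apart is not known.

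Rapid immediate early genes rose in 26 of 34 tested members, and in 28 adjusted over the list alone, with a median log2 fold change of 0.92 (camera adjusted p = 3.55e-46), and adjusted p = 0.182 with an estimated correlation. All 8 of the genes fixed for naming passed: besides Fos, Npas4 and Arc at 1.72 (SE 0.087), they were Junb at 1.66 (SE 0.084), Dusp1 at 1.47 (SE 0.0809), Fosb at 1.02 (SE 0.0815), Nr4a1 at 0.98 (SE 0.0766) and Egr1 at 0.51 (SE 0.0801), with an edgeR adjusted p of at most 1.26e-05. Delayed activity-regulated genes rose in 10 of 26 members, with 17 higher and 1 lower (Inhba) adjusted over the list alone (camera adjusted p = 1.58e-12), and adjusted p = 0.182 with an estimated correlation. Among them, Tiparp, a poly-ADP-ribose polymerase, was 2.14-fold higher (log2 SE 0.0952, adjusted p = 9.41e-14) and Nr4a3 was 1.75-fold higher (log2 SE 0.0766, adjusted p = 3.26e-12). ERK pathway feedback regulators rose in 4 of 15 members (Dusp1, Dusp5, Dusp6 and Spry4), and in 7 adjusted over the list alone (camera adjusted p = 1.72e-08), with adjusted p = 0.182 with an estimated correlation. Of those 4, Dusp1 and Dusp6 are also on the rapid list and Dusp5 on the delayed list, so only Spry4 adds to the genes already counted. Dusp5, an ERK phosphatase, was 1.82-fold higher (log2 SE 0.0916, adjusted p = 1.72e-10).

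Blood cell markers rose in 3 of 4 tested members, the globin genes Hba-a1, Hba-a2 and Hbb-bs, over all genes and adjusted over the list alone (camera adjusted p = 8.55e-08), and adjusted p = 0.182 with an estimated correlation. Hba-a1 was 2.91-fold higher (log2 SE 0.0829, adjusted p = 6.13e-23) and averaged 49.1 ± 3.86 CPM (SD, n = 2) after defeat and 16.9 ± 0.287 CPM (SD, n = 2) in home-cage mice. Hbb-bs was 2.30-fold higher (log2 SE 0.12, adjusted p = 2.49e-11). Hba-a1 and Hba-a2 are near-identical copies on chromosome 11, at 32283511 to 32284465 and 32296489 to 32297298, and reads may be assigned to either. The leukocyte gene Ptprc, the other tested member, had a log2 fold change of -0.05 (SE 0.121).

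Meningeal fibroblast markers rose in 1 of 9 members, Fmod, a collagen-binding proteoglycan, at 0.67 (SE 0.138, edgeR adjusted p = 0.0024), with 4 higher adjusted over the list alone (camera adjusted p = 0.00234), and adjusted p = 0.717 with an estimated correlation. In 7 other lists that camera called, 0 members passed over all genes. Higher were glucocorticoid-responsive genes (median log2 fold change 0.14, camera adjusted p = 0.00234; adjusted p = 0.284 with an estimated correlation), heat shock and chaperone genes (median 0.10, adjusted p = 0.00511; adjusted p = 0.359 with an estimated correlation) and cytosolic ribosomal protein genes (median 0.04, adjusted p = 0.00511; adjusted p = 0.786 with an estimated correlation). Circadian clock genes (median 0.10, adjusted p = 0.023, and adjusted p = 0.359 with an estimated correlation) and interferon-stimulated genes (median 0.09, adjusted p = 0.0306, and adjusted p = 0.717 with an estimated correlation) were also called higher. Per1, a clock gene that is also on the rapid and glucocorticoid lists, had 0.28 (SE 0.0759), the chaperone gene Dnajb1 0.26 (SE 0.0777) and the interferon regulator Irf7 0.36 (SE 0.168). Called lower were oligodendrocyte markers, with 14 of 15 members negative (median -0.11, camera adjusted p = 0.00688, and adjusted p = 0.723 with an estimated correlation), and microglia markers, with 11 of 11 negative (median -0.07, adjusted p = 0.0223, and adjusted p = 0.717 with an estimated correlation). Adjusted over the list alone, the genes lower included Cldn11, Mbp, Mobp and Trem2, and Per1, Bhlhe40 and Dnajb1 were higher. The myelin gene Mobp had -0.24 (SE 0.0767) and the microglial receptor gene Trem2 -0.35 (SE 0.106). Camera did not call the other 10 lists. Its adjusted p was 0.429 for replication-dependent histone genes, of which the linker histones H1f3 at -0.46 (SE 0.109) and H1f4 at -0.40 (SE 0.0842) passed as lower; adjusted over the list alone, 4 were higher and 3 lower, so the median (0.03) and the mean (-0.01) differ in sign. It was 0.41 for choroid plexus and ependymal markers, 0.812 for endothelial and mural markers, 0.835 for astrocyte markers, 0.417 for oligodendrocyte precursor markers, 0.922 for interneuron markers, 0.363 for basal forebrain, septal and thalamic markers, 0.812 for striatal markers, 0.795 for cortical markers and 0.676 for glutamate and GABA-A receptor subunits. Median and mean also differed in sign for the striatal and interneuron markers.

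**Figure D3:**
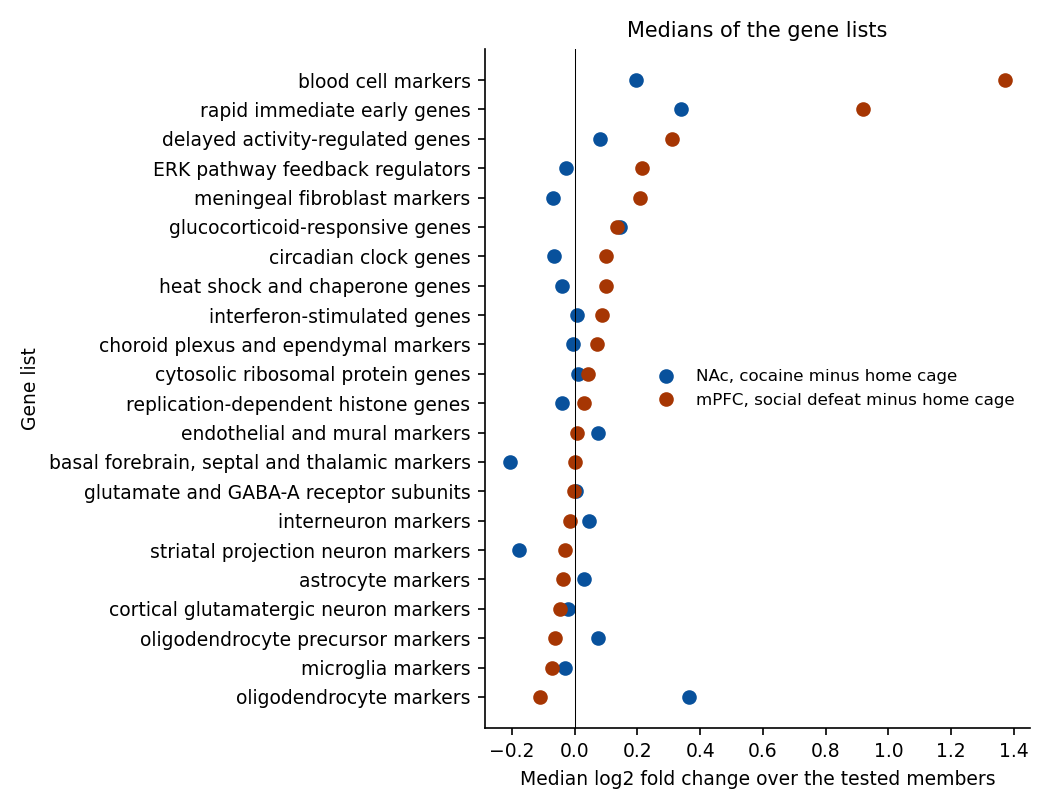
Median log2 fold change of each gene list after cocaine in NAc and after social defeat in mPFC, with 1 point per list and comparison. Rapid immediate early genes had medians of 0.34 in NAc and 0.92 in mPFC, and blood cell markers 0.20 and 1.37.

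The lowered genes with the largest changes that met the naming rule were Zc3h7a, a zinc finger gene, which fell by 1.79 on the log2 scale (SE 0.206, adjusted p = 2.04e-09), Cdk8, a kinase of the Mediator complex, which fell by 1.18 (SE 0.112, adjusted p = 3.26e-12), and Lars2, a mitochondrial leucyl-tRNA synthetase, which fell by 0.92 (SE 0.103, adjusted p = 8e-10). Cby3 fell by 0.73 (SE 0.137), Thbs4, a thrombospondin, by 0.70 (SE 0.183), Frmpd2 by 0.68 (SE 0.16), Bub1b, a mitotic checkpoint kinase, by 0.65 (SE 0.142) and Cstad by 0.63 (SE 0.112), with adjusted p between 0.000194 and 0.0464. Zc3h7a, Cdk8 and Lars2 varied between libraries with CT010467.1, a ribosomal RNA gene named after its values were seen, which fell by 1.74 (SE 0.221, adjusted p = 4.95e-08). CT010467.1 held 0.0492% and 0.0119% of counts in defeat replicates 1 and 2, 0.0704% and 0.132% in mPFC home-cage replicates 1 and 2, and 0.0126% in NAc cocaine replicate 1 against 0.0876% in NAc cocaine replicate 2.

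**Figure D4:**
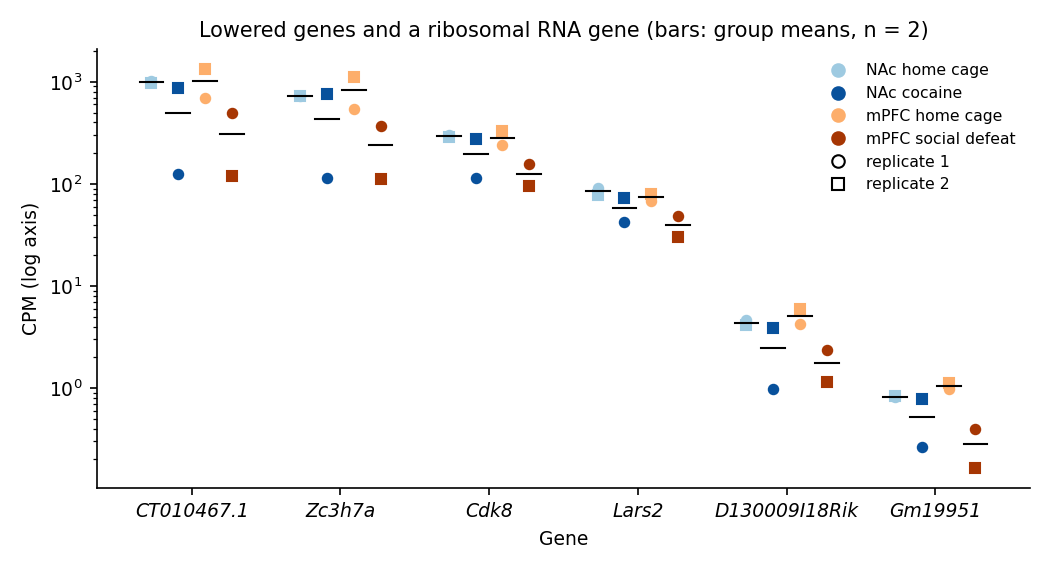
CPM (log axis) of the ribosomal RNA gene CT010467.1 and of genes lower after social defeat in each library, with points for single libraries and bars for group means (n = 2). NAc cocaine replicate 1 was the lowest NAc library for Zc3h7a, with 15681 counts against 108796 in cocaine replicate 2.

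The count of changed genes depended on single libraries: it was 238 without mPFC home-cage replicate 1 and 58 without defeat replicate 2, and a single fit of all 8 libraries, which shares the larger spread of the NAc libraries, passed 5 (Dusp1, Egr2, Fosb, Npas4 and Ovca2). Among lists, the calls for rapid, delayed, ERK feedback and blood genes held without each mPFC library in turn, and 8 others were lost without home-cage replicate 1 (glucocorticoid, heat shock, circadian, interferon, oligodendrocyte, microglia, meningeal and ribosomal protein genes). Without defeat replicate 2, 7 of the 12 calls remained, and interferon-stimulated genes turned down (adjusted p = 0.909). Without defeat replicate 1 the circadian, oligodendrocyte and ribosomal protein calls were lost, and without home-cage replicate 2 the microglia call was. Thbs4 had -0.12 without home-cage replicate 1, H1f3 -0.23 without home-cage replicate 2, and Fmod 0.40 without home-cage replicate 1 and 0.43 without defeat replicate 2. None of these 3 then passed. Zc3h7a ranged from -2.91 without defeat replicate 1 to -1.17 without defeat replicate 2, and Lars2 was -0.61 without defeat replicate 2. Frmpd2, Bub1b, Cstad and H1f4 did not pass without defeat replicate 2, and the DESeq2 Wald test did not pass Zc3h7a, Cdk8, Lars2, Bub1b, Frmpd2, Thbs4, Fmod and H1f3.

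The third comparison asked which genes responded differently to cocaine in NAc and to social defeat in mPFC. Region and experience differ together, so it separates neither. Among genes lower in the cocaine response than in the defeat response, the 5 with the smallest p were Dusp1, with a difference of log2 fold changes of -0.80 (SE 0.143), Hba-a1 at -1.22 (SE 0.224), Ovca2 at -0.93 (SE 0.137), Pdp1 at -0.45 (SE 0.0919) and Slc4a1, the anion exchanger of red blood cells, at -2.44 (SE 0.544). In the other direction the 5 with the smallest p were Kcne1, a potassium channel subunit, at 3.25 (SE 0.598), Prss38 at 2.78 (SE 0.651; 3.38 without defeat replicate 1), Lrrc63 at 1.74 (SE 0.405), Skap1 at 0.80 (SE 0.183) and Xdh, xanthine dehydrogenase, at 0.73 (SE 0.173). None of them passed in the edgeR fit without a covariate. Kcne1 averaged 0.0157 CPM in NAc home-cage mice and Prss38 0.0223 CPM after defeat, so their large differences rest on few counts. With the striatal minus cortical score as a covariate, chosen after seeing the data, 10 genes passed, among them Hba-a1 at -1.20 (adjusted p = 0.00143), Ovca2 at -0.94 (adjusted p = 0.0176), Dusp1 at -0.80 (adjusted p = 0.0358) and Skap1 at 0.79 (adjusted p = 0.0482). In simulated data this fit made 18 false calls among 161. The simulated means were built with the same score, so that share does not cover the choice of the covariate.

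Of 18783 genes tested for a difference between the responses, edgeR without the covariate passed 0, with 415 at an unadjusted p under 0.05 where chance gives 939. The DESeq2 Wald test passed 2, Hba-a1 at -1.21 (adjusted p = 0.0119) and Ovca2 at -0.92 (adjusted p = 0.00792). Without NAc home-cage replicate 1, edgeR passed 1 gene, Lgr6 at -3.17 (adjusted p = 0.00189), which was named after its value was seen. Rapid immediate early genes had a negative difference in 33 of 34 members, with a median of -0.39 (camera adjusted p = 9.65e-16), and adjusted p = 0.32 with an estimated correlation; adjusted over the list alone, Dusp1 was lower. Blood cell markers had a median of -0.91 (camera adjusted p = 0.00117), and adjusted p = 0.32 with an estimated correlation, with Hba-a1 and Hbb-bs lower adjusted over the list alone. Among the 8 lists called, the rapid, ERK feedback and blood calls held without each of the 8 libraries in turn. Oligodendrocyte markers had a positive difference in 15 of 15 members, with a median of 0.51 (camera adjusted p = 4.97e-06), and adjusted p = 0.559 with an estimated correlation. That call was lost without NAc home-cage replicate 2 (adjusted p = 0.106), as was the heat shock call (adjusted p = 0.15). Delayed activity-regulated, ERK feedback, heat shock, circadian and meningeal lists were also called lower. The delayed call was lost without cocaine replicate 1, NAc home-cage replicate 2 or mPFC home-cage replicate 1, the circadian call without cocaine replicate 2 or NAc home-cage replicate 1, and the meningeal call without mPFC home-cage replicate 1 or defeat replicate 2. Of the 8 calls, 0 held with an estimated correlation. That setting called 0 lists in each comparison. It did not call the striatal list between regions, where 20 of 20 members were positive. A missing call with an estimated correlation therefore does not by itself decide about a list. The fry p was 0.0461 for the rapid and 0.00361 for the blood list, and 0.0602 to 0.286 for the other lists called here. After defeat it was at most 0.00569 for the rapid, delayed, ERK feedback and blood lists, and 0.0195 to 0.497 for the other called lists. Oligodendrocyte markers after cocaine had an estimated correlation of 0.994 and a fry p of 0.417, so their members were not separate evidence.

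Whether the same genes responded in both experiments was asked over the 17722 genes tested in both. No library is shared between them. The number changed in both was 0 in the reported edgeR fits, because 0 genes passed in NAc. The edgeR fit with the replicate number as a block passed 38 genes in NAc, and its overlap with the defeat response was not counted. Those 38 included Npas4, Fos and Arc, which also rose after defeat. With the covariate, chosen after seeing the data, the number changed in both was 39. Of these, 34 were higher in both, where 2.03 are expected by chance, and 5 lower in both (CT010467.1, Cdk8, D130009I18Rik, Lars2 and Zc3h7a). Among the NAc libraries, each of these 5 was lowest in cocaine replicate 1. Zc3h7a had 113 and 761 CPM in cocaine replicates 1 and 2, and 733 and 724 in the NAc home-cage libraries. The genes lower in both include a ribosomal RNA gene, CT010467.1, and genes that varied with it. The DESeq2 Wald test gave 4, all higher in both, which are Npas4, Egr2, Fosb and Ccn1. Of 98 genes raised by social defeat in mPFC, 86 (87.8%) had a positive log2 fold change after cocaine in NAc, against 47.1% of the other genes (Fisher's exact p = 7.38e-17), where genes are not independent replicates. Of those 98, 22 (22.4%) were positive with an unadjusted p under 0.05 in NAc, against 0.74% of the other genes (Fisher's exact p = 1.82e-25). Across the raised genes, Pearson's r between the log2 fold changes was 0.708, and across all genes it was 0.097, with a Spearman rho of 0.022. Of 28 genes lowered by social defeat, 15 were negative in NAc, with a median of -0.006. Ccn1 had log2 fold changes of 2.68 in mPFC and 1.91 in NAc, Btg2 2.25 and 1.27, Fos 2.09 and 1.73, and Npas4 2.03 and 1.69. The NAc value of Fos rests on home-cage libraries that differ, and was 1.06 without replicate 1 and 3.0 without replicate 2. Hba-a1 had 1.54 in mPFC and 0.33 in NAc, where it was 0.07 without cocaine replicate 1 and 0.55 without cocaine replicate 2. Gh had 2.02 in mPFC, and in NAc its libraries overlapped, with 59 and 15 counts after cocaine and 13 and 46 in home-cage mice.

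**Figure D5:**
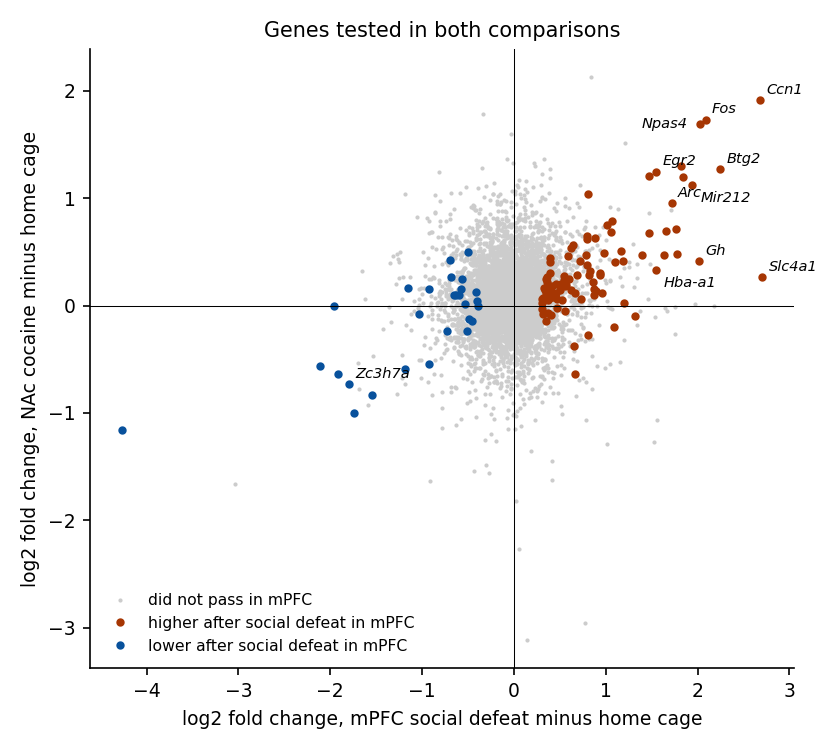
Log2 fold change after social defeat in mPFC (horizontal axis) and after cocaine in NAc (vertical axis), with 1 point per gene tested in both. Of the 98 genes raised by defeat, 86 lie above 0 on the vertical axis, and 15 of the 28 lowered genes lie below 0.

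The fourth comparison, of NAc with mPFC in home-cage mice, asked how the dissected regions differ. Each region has its own count table, so a batch shared within a table is not separated from region. Markers of striatal projection neurons were higher in NAc and several markers of cortical projection neurons were lower. Six3, a transcription factor of striatal development, averaged 34.6 ± 30.1 CPM (SD, n = 2) in NAc and 0.0255 ± 0.0152 CPM (SD, n = 2) in mPFC. Drd2 averaged 168 ± 156 CPM (SD, n = 2) in NAc and 2.48 ± 0.117 CPM (SD, n = 2) in mPFC. Fezf2 averaged 6.02 ± 4.31 CPM (SD, n = 2) in NAc and 59.5 ± 5.98 CPM (SD, n = 2) in mPFC.

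Of 18300 genes tested, 1283 were higher and 979 lower in NAc, 807 and 587 of them by more than 2-fold. Striatal markers were higher in 16 of 20 members, and in 20 adjusted over the list alone (camera adjusted p = 2.1e-09), with adjusted p = 0.54 with an estimated correlation. Several of these genes had few counts in mPFC. Six3 had 11738 counts in NAc and 6 in mPFC, a ratio of 1530 after scaling to library size (95% counting interval 703 to 4170), Isl1, a transcription factor, a ratio of 328 (128 to 1200) and Drd3, the dopamine D3 receptor, a ratio of 345 (215 to 593). Ankk1, the neighbour of Drd2 on chromosome 9, had a ratio of 173 (103 to 318) and the desmoglein gene Dsg1c 192 (97.3 to 445). These intervals cover counting error only, and the ratios differ between the NAc libraries: taken from replicate 1 and from replicate 2 alone, they were 2270 and 555 for Six3, 507 and 91.4 for Isl1, 538 and 91.3 for Drd3, 269 and 47.3 for Ankk1 and 287 and 67.2 for Dsg1c. Vmn1r206, named for a vomeronasal receptor, had 299 and 48 counts in NAc replicates 1 and 2 and 0 in mPFC. Against a floor of 3 counts over the mPFC group it was at least 90.5-fold higher in the 2 NAc libraries together and at least 29-fold higher in replicate 2 alone. Ndst4, a heparan sulfate enzyme, was 116-fold higher (log2 SE 0.241, adjusted p = 0.00142) and Serpina9 151-fold higher (log2 SE 0.975, adjusted p = 0.0146). Drd2 was 67.5-fold higher (log2 SE 0.839, adjusted p = 0.0153). The log2 fold change of Drd2 was 4.55 without NAc home-cage replicate 1 and 6.80 without replicate 2, and that of Serpina9 5.69 and 7.97. Drd2 did not pass without mPFC home-cage replicate 1 (adjusted p = 0.193) or 2 (adjusted p = 0.189). Per GENCODE M21, Six3 lies on chromosome 17 at 85613608 to 85629302 and Drd3 on chromosome 16 at 43754026 to 43822932.

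Cortical glutamatergic markers were lower in 5 of 16 members (among them Cux2, Fezf2, Kcnv1 and Mef2c), and in 8 adjusted over the list alone (camera adjusted p = 0.000428), with adjusted p = 0.54 with an estimated correlation. Fezf2 fell by 3.31 (SE 0.528, adjusted p = 0.0213) and Cux2 by 1.92 (SE 0.173, adjusted p = 0.00642), as log2 fold changes from mPFC to NAc, and Neurod6 did not pass at -1.74 (SE 0.442). Without NAc home-cage replicate 1 or 2 in turn, Fezf2 had -2.71 and -4.33, and Neurod6 -1.20 and -2.61, both of which passed. The NAc level of the cortical genes Slc17a7, Tbr1 and Neurod2 was 58.6%, 61.8% and 76.3% of that in mPFC, named after their values were seen. These shares depended on the library: NAc home-cage replicates 1 and 2 had 468 and 1050 CPM of Slc17a7, 103 and 206 of Tbr1 and 53.9 and 104 of Neurod2, against mPFC means of 1290, 250 and 104, so Neurod2 in replicate 2 was at the mPFC mean. The largest decreases in NAc that met the naming rule were Krt80, a keratin, at -4.95 (SE 0.631), Hkdc1, a hexokinase family gene, at -4.88 (SE 0.274), Clec18a at -4.88 (SE 0.401), Exph5 at -4.78 (SE 0.293), Osr1, a transcription factor, at -4.71 (SE 0.23), Xirp2 at -4.60 (SE 0.209), Smoc2 at -4.58 (SE 0.474) and Mylk3 at -4.24 (SE 0.397), with adjusted p between 0.00207 and 0.0129. Their order depended on single libraries: without NAc home-cage replicate 1 or 2 in turn, Krt80 had -4.19 and -6.36, Clec18a -4.37 and -5.56, Smoc2 -4.04 and -5.38, and Mylk3 -3.71 and -4.97.

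Interneuron markers went both ways, with 4 of 14 higher and 3 lower (camera adjusted p = 0.965): Pvalb, the parvalbumin gene, fell by 2.60 (SE 0.301, adjusted p = 0.0104) and Adarb2 rose by 1.42 (SE 0.18, adjusted p = 0.0128). Of the glutamate and GABA-A receptor subunits, 5 of 34 were higher and 6 lower (camera adjusted p = 0.965), among them Grm8 at -1.96 (SE 0.23, adjusted p = 0.0106). Basal forebrain, septal and thalamic markers were higher in 3 of 11 (camera adjusted p = 0.0243), with Nts, the neurotensin gene, 15.5-fold higher (log2 SE 0.463, adjusted p = 0.0105), and histone genes in 4 of 20 (camera adjusted p = 0.00052), with H3c2 15.9-fold higher (log2 SE 0.611, adjusted p = 0.0195). Nts had a log2 fold change of 3.36 without NAc home-cage replicate 1, and H3c2 3.13 without NAc home-cage replicate 2. Rapid immediate early genes were lower in 8 of 34 (camera adjusted p = 0.000949) and ERK feedback regulators in 5 of 15 (camera adjusted p = 0.00317), with Etv5 at -1.02 (SE 0.111, adjusted p = 0.00912). Each of these 4 called lists had adjusted p = 0.54 with an estimated correlation. Camera also called glucocorticoid-responsive genes, astrocyte, microglia, meningeal and blood markers lower, and 0 of the 11 calls held with an estimated correlation. Among choroid plexus markers, which camera did not call, Otx2 had 256 counts in NAc and 1 in mPFC, a ratio of 200 (95% counting interval 35.6 to 7940). That count was in mPFC home-cage replicate 1, and replicate 2 had 0. Otx2 did not pass without either mPFC home-cage replicate. Without replicate 2 its log2 fold change was 6.59. Without replicate 1 the mPFC group had 0 counts, so no fold change is given.

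The regional count depended on single libraries. It was 5518 without NAc home-cage replicate 1 and 8048 without NAc home-cage replicate 2, where the spread comes from the mPFC libraries alone, and 0 without either mPFC home-cage replicate, where it comes from the NAc libraries alone and edgeR had 2680 (without replicate 1) and 2724 (without replicate 2) genes at an unadjusted p under 0.05. The DESeq2 Wald test passed 3683, and a single fit of all 8 libraries 4654. In simulated data at this spread, edgeR made 22 false calls among 123, and recovered 50.7% of 2-fold changes. That simulation changed 200 genes, whereas 2262 passed in the data, so its share of false calls does not carry over to them. Of the list calls, those for striatal, cortical, rapid immediate early, ERK feedback, basal forebrain and histone genes held without each of the 4 libraries. The meningeal call was lost without NAc home-cage replicate 1 or 2 or mPFC home-cage replicate 2, the astrocyte and microglia calls without NAc home-cage replicate 1, the blood call without NAc home-cage replicate 2 or mPFC home-cage replicate 1, and the glucocorticoid call without mPFC home-cage replicate 2.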

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

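The newer quasi-likelihood fit and the score covariate were chosen after seeing the data, and the other alternatives before. The cause of the differences was not tested except where the construction of an alternative shows it. Scaling, filters, robust, legacy and newer fits and factors without ribosomal RNA kept each count of changed genes within 1.5 times the reported one, and no scaling moved the median of all genes by more than 0.035 on the log2 scale. For cocaine in NAc, where edgeR passed 0 genes, the DESeq2 Wald test passed 4 and the covariate fit 461. The replicate number as a block passed 38 genes for cocaine (33 higher, 5 lower, the higher ones including Npas4, Egr2, Fosb, Fos, Arc, Junb, Dusp1, Btg2 and Ccn1), 2174 between regions and 3 lists for cocaine in place of 4; the labels do not say that the number marks a batch, and the deviations of number 1 from number 2 in the 2 NAc groups correlate at r = 0.817 across genes, which are not independent replicates. Leaving out 1 NAc library at a time gave 0 changed genes for cocaine each time.

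For social defeat, a single fit of all 8 libraries passed 5 genes in place of 127, since it shares the larger spread of NAc, and leaving out 1 library gave 58 to 238. Between regions, an adjusted p under 0.10 passed 4115 genes, the DESeq2 Wald test 3683, the fit of all 8 libraries 4654, and leaving out 1 library 0 to 8048. For the difference between responses, the DESeq2 Wald test passed 2, the covariate fit 10, and leaving out 1 library 0 to 1. An estimated correlation between genes called 0 lists for cocaine, 0 for defeat, 0 between regions and 0 for the difference; leaving out 1 library gave 4 to 12 list calls for defeat. On simulated data with a single list raised 1.5-fold, camera with the preset correlation called it (adjusted p = 4.63e-54) and with an estimated correlation did not (adjusted p = 0.0666). Genes were drawn independently there, so that simulation could not show false calls of the preset correlation among genes that vary together. After cocaine the estimated correlation was 0.994 for oligodendrocyte markers and 0.996 for striatal markers. The number of genes changed in both responses was 4 with the DESeq2 Wald test and 39 with the covariate fit (34 higher and 5 lower in both).

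No named gene that passed changed sign under any alternative run. Of 30 named genes that passed after defeat, 22 passed with the DESeq2 Wald test, 27 with the robust fit and 3 in the fit of all 8 libraries; of 48 between regions, 48 passed with the DESeq2 Wald test and 0 without either mPFC home-cage library. Genes in the regional comparison with under 10 counts in mPFC are limited by depth, as their counting intervals show. In simulated data at the mPFC spread, edgeR recovered 80.6% of 1.5-fold changes, with 8 false calls among 187. False calls were 20 among 102 at the spread of the cocaine comparison and 22 among 123 between regions. For the difference they were 8 among 79, and 18 among 161 with the covariate. In these last simulations the share of false calls exceeded the 0.05 of the adjusted p threshold. Libraries were drawn independently there, whereas the NAc libraries deviated together by number. In the cocaine simulation 4.57% of unchanged genes had an unadjusted p under 0.05, while 211 of all 18418 genes did in the data. The shares for cocaine and the difference therefore do not carry over to the reported fits. Between regions 200 genes were changed in the simulation, whereas 2262 passed in the data, so that share does not carry over either.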

Other observations

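Among the tests below, those of tissue shares, of the 5 lowered genes, of red blood cells and of vessels were chosen after the result was seen. Genes in this part were named after their values were seen. The genes that follow rose in edgeR after social defeat in mPFC, and no theme among them was tested. Atf3, Klf2, Klf4, Gadd45b, Gadd45g and Zfp36 are among the rapid-list members counted above, and Homer1 and Bdnf among the delayed-list members. Atf3, a stress-induced transcription factor, rose by 1.47 (SE 0.256, adjusted p = 0.000115) on the log2 scale, and the Krüppel-like factors Klf2 and Klf4 by 0.94 (SE 0.0999, adjusted p = 1.91e-10) and 0.90 (SE 0.118, adjusted p = 1.14e-07). The growth arrest genes Gadd45g and Gadd45b rose by 1.07 (SE 0.115, adjusted p = 2.94e-10) and 0.80 (SE 0.108, adjusted p = 2.96e-07). Zfp36, whose protein binds AU-rich elements and destabilises mRNA, rose by 0.94 (SE 0.126, adjusted p = 2.19e-07), and its relatives Zfp36l1 and Zfp36l2 by 0.36 (SE 0.0807, adjusted p = 0.00797) and 0.46 (SE 0.0868, adjusted p = 0.000551). Homer1, a postsynaptic scaffold gene with an activity-induced short form, rose by 0.88 (SE 0.0849, adjusted p = 7.9e-12), and Bdnf, a neurotrophin gene, by 0.39 (SE 0.0793, adjusted p = 0.00179). Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose by 1.06 (SE 0.173, adjusted p = 3.05e-05).

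Beside Gh, the pituitary hormone gene Prl had 16 and 22 counts after defeat and 3 and 8 in mPFC home-cage mice (log2 fold change 1.62, SE 0.552, adjusted p = 0.261). It had 0 counts in all 4 NAc libraries. In NAc, some genes were high in a single home-cage library: Eomes had 261 counts in replicate 2 and 8 in replicate 1, and Calcr 11 and 205, against 10 to 20 counts of either gene in the cocaine libraries.

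NAc libraries with the same number deviated together in both treatment groups. The striatal minus cortical score differed between number 1 and number 2 by at least 1.93 log2 units in both groups, in the same direction, which is consistent with different shares of striatum and cortex in the dissected pieces. Genes with a regional difference under 0.25 on the log2 scale still deviated together (r = 0.647 across genes, against 0.908 for genes with a difference over 1), which a preparation batch shared by number could also give, although their deviations were smaller (SD 0.165 and 0.238, against 0.67 and 0.883). Both explanations stay open, and each may act in addition to the other. No group of the design differs by number, so no biological explanation was tested.

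Genes lower after social defeat may in part follow carry-over of ribosomal RNA rather than the experience. Of the 5 lowered genes with the smallest p besides CT010467.1 itself (Cdk8, D130009I18Rik, Lars2, Zc3h7a and Gm19951), 5 were lowest in NAc cocaine replicate 1, the NAc library with the lowest share of CT010467.1, where no mouse met social defeat. Of the other 22 lowered genes, 7 (31.8%, exact 95% interval 13.9% to 54.9%, chance 25%) were lowest there, so for these carry-over and an effect of defeat cannot be told apart at this number of genes. An effect of social defeat on any of the lowered genes stays open, since CT010467.1 itself was lower in both defeat libraries than in both mPFC home-cage libraries.

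Globin transcripts were higher after social defeat. More blood vessels in the dissected pieces are argued against, since the endothelial and mural list had a median log2 fold change of 0.008, with 8 of 16 members positive. Adjusted over that list alone, 1 of the 16, Vwf, was higher. More red blood cells left in the tissue could raise globin genes: of 12 erythroid genes outside the globin clusters, 5 were tested, with a median of 0.44 (SD 1.29), and Slc4a1 passed at 2.71 (SE 0.359, adjusted p = 1.58e-07) on 57 and 89 counts against 11 and 9. Klf1, another of the 5, had -0.32 (SE 0.333), so red blood cells and a response of brain cells cannot be told apart, with too few counts in the erythroid genes to decide. Social defeat itself, by way of blood flow or of transcription, stays open and untested.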
